A study of Homo sapiens with 3 samples.

How the data were processed

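The data are 3 dual-colour Agilent oligonucleotide arrays of 1 design, each on a slide of its own. Per the labels, total RNA of UACC62 melanoma cells at day 3 was hybridised, with RNA of cells carrying a lentiviral shRNA against p62 in the Cy5 (red) channel and RNA of cells carrying a non-targeting shRNA in the Cy3 (green) channel. All arrays have the same dye orientation, so a gene-specific dye effect cannot be separated from the effect of the shRNA. A single shRNA against p62 is named in the labels. The labelling protocol in the labels names a kit for single-colour work, while the labels' channels and the files hold both dyes, and the files were read as dual-colour arrays. The series text calls the replicates biological. All arrays were scanned on the same day and lie on different slides, so neither could be tested as a batch, and whether they were labelled or hybridised together is not given in the sources used here.

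Per the file headers, the scans were read with Agilent Feature Extraction 10.7.1.1 on a grid of 532 rows and 85 columns, which gave 45015 spots per array. The deposited scanner files give the intensity of each spot and of its local background as median pixel brightness in each channel, with no normalization. They also give processed intensity values, which per the file headers were background-subtracted and dye-normalized, and a log ratio, which per the file headers is the log10 of red over green processed signal. The authors' series matrix holds a log2 ratio of red over green per spot, as found by setting each column against the scanner values of its array. Its medians were 0.0077, -0.0013 and 0.0076, and it correlated with the loess-normalized ratio of its own array with r = 0.991, 0.952 and 0.989, against at most 0.856 for another array. Per the submitters' processing notes limma was used, and the steps behind the matrix are not given in the sources used here. The matrix is thus on the log2 scale, centred near 0 and in the direction red over green.

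The ratios were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50, log2 ratios were normalized within each array by loess with control spots and outlier spots at weight 0, and no scaling was done between arrays. The design fixed before the data were examined named mean signals, and median signals were used since the scanner files used here give those. Control spots and spots marked by the software as non-uniform or population outliers were removed (86, 811 and 121 non-control spots on replicates 1, 2 and 3), and no spot was saturated. Spots of the same probe were averaged. A probe was kept if it was well above background in either channel on at least 2 of the 3 arrays. Pooled over 264 probes with 5 or more spots, the SD of the log2 ratio between spots was 0.059, 0.156 and 0.057 on replicates 1, 2 and 3.

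Probes were named through their RefSeq accessions without versions in a table of the assembly GRCh38.p14, which differs from the build of the array's annotation, so no coordinates are given. Of 41000 probes 23680 (57.8%) matched a current symbol, covering 16422 genes, and the 17320 others were tested apart. The brightest probe that passed the filter stood for its gene, and 2332 genes were left out, most of them as dim and the others because outlier spots left them fewer than 2 arrays. The 14090 genes left were tested, of which 329 were measured on 2 arrays. No column of per-sample values was left unused for want of a label.

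Each array is 1 replicate, and its ratio pairs the 2 RNAs. An intercept was fitted to the 3 log2 ratios of each gene with limma's lmFit and eBayes (prior degrees of freedom 5.72), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact sign-flip test of 3 arrays cannot go below p = 0.25, so p-values of single genes rest on limma's shared variance. Gene lists, 35 in number, were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 over genes measured on all 3 arrays, with Benjamini-Hochberg adjustment over the lists and at least 5 genes per list. The genes named in the text are SQSTM1, FERMT2 (known from the study), the 10 largest and 10 smallest log2 ratios among genes past the threshold with the same direction on all 3 arrays, and in each list up to 4 measured members with the smallest adjusted p. Members that complete a count of 5 or fewer (such as ABCC1 or KLF6) and NFE2L2 were named in addition, after their values were seen. Some genes the rule selects are not reported here. Values are mean log2 ratios of shp62 over shControl with the SD over arrays, and n is 3 unless given.

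On simulated data with the spread of these arrays and 14095 genes, the test recovered 43.3% of genes changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and 97.0% of those changed by 2, and 5 of 153 called genes were unchanged. In that simulation 67, 67 and 66 genes were changed at these sizes, far fewer than were called in the data. Its arrays shared the same dye trend, with no outlier spots and no dye bias of single probes. The simulation thus does not gauge false calls from such sources. In separate simulated values the NRF2 list, lowered by 0.5, was found, with 0 other lists called. Those values were drawn independently for each gene with a common spread. They thus say nothing of false calls in lists whose genes vary together. The alternatives tried were other background corrections, the processed intensity values, median centring, scale and quantile-type normalization between arrays, and the authors' matrix. Also tried were other filters and probe summaries, a variance trend, array weights, other thresholds, each replicate left out, and other set tests. The quantile-type normalization equalised intensities and left each probe's log2 ratio unchanged, so it could change only which probe stood for a gene. The variance trend did not enter the set test of lists, where that alternative repeated the main result.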

Results

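Messenger RNA levels were compared on 3 dual-colour oligonucleotide arrays in UACC62, an established human melanoma cell line. Each array carried RNA of cells depleted of p62 by a stable lentiviral shRNA, labelled with Cy5, against RNA of cells with a non-targeting shRNA, labelled with Cy3, both taken at day 3. The series text calls the 3 pairs biological replicates, and each array is 1 replicate of the comparison. The protein p62, encoded by SQSTM1, is a receptor that delivers cargo to autophagy and a scaffold in several signalling pathways. The series title ties p62 to the decay of mRNA in melanoma, and the comparison asks which transcripts differed in abundance once p62 was depleted. Of the 43376 non-control spots on each array, 77.6%, 78.3% and 79.7% were well above background in the red channel of replicates 1, 2 and 3, and 75.3%, 76.8% and 77.5% in the green channel. Gene-level log2 ratios of replicates 1 and 2 correlated across genes with r = 0.85, those of 1 and 3 with r = 0.86 and those of 2 and 3 with r = 0.80, where genes are not independent replicates. Replicate 2 stood apart technically: 811 of its non-control spots were marked as outliers by the scanner software, against 86 and 121 on replicates 1 and 3. The small number of arrays limits the precision of every value below.

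SQSTM1, the target of the shRNA, was 6.19-fold lower in depleted cells, with a log2 ratio of -2.63 ± 0.13 (SD, n = 3) and a limma adjusted p = 2.41e-06. It fell on each of the 3 arrays and was read by 1 probe. FERMT2, which encodes an activator of integrins known as kindlin-2, fell as well, by 2.27-fold (log2 ratio -1.18 ± 0.25, n = 3, limma adjusted p = 1.05e-04). Across 14090 genes, 5724 (40.6%) differed at an adjusted p under 0.05, of which 2572 were higher and 3152 lower in depleted cells, and 5715 of them had 1 direction on all arrays measured. The balance turned with the authors' matrix (3538 higher, 3143 lower) and with the processed signals of the scanner software (3484 higher, 3186 lower). Most differences were small, with a median absolute log2 ratio of 0.40 among the changed genes. At least a 2-fold difference was found for 345 of them, of which 61 were higher and 284 lower, and at least a 4-fold difference for 23, of which 2 were higher and 21 lower. No dyes were swapped, so a bias of a gene's probe towards 1 dye stays in its ratio. With each array centred on its median in place of loess, limma called 0 genes higher and 7 lower and SQSTM1 had an adjusted p = 0.0555, with arrays scaled to a common spread over all spots it called 0 genes, with 4259 at an unadjusted p under 0.05 and SQSTM1 at an adjusted p = 0.161, and without replicate 1 it called 3122.

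The 10 most lowered genes among those measured on all 3 arrays belong to varied processes, and 6 of them fell by more than SQSTM1 itself. NAP1L1, a histone chaperone of nucleosome assembly, was 13.1-fold lower (log2 ratio -3.71 ± 0.13, n = 3, limma adjusted p = 7.90e-07). HSPA13, a chaperone-like protein of the heat shock family, had a log2 ratio of -3.00 ± 0.70, and CEP20, a centrosomal protein, one of -2.96 ± 0.03. The acetyltransferase gene KAT2B fell to a log2 ratio of -2.80 ± 0.21, RPIA of the pentose phosphate pathway to -2.76 ± 0.23 and the sulfate transporter gene SLC26A2 to -2.72 ± 0.28. SQSTM1 came next, ahead of the trans-Golgi protein gene TGOLN2 (-2.58 ± 0.12), SOAT1, which esterifies cholesterol (-2.43 ± 0.75), and NMD3, an adaptor for export of the large ribosomal subunit (-2.30 ± 0.04). Other probes of these genes lay closer to 0, at a log2 ratio of -0.41 for HSPA13, -0.71 for CEP20, -1.96 for KAT2B, -1.42 for TGOLN2, -1.96 for SOAT1, and -1.85 and -1.41 for NMD3. By the rule of choice these other probes were dimmer, for CEP20 at a log2 intensity of 8.76 against 13.0. NAP1L1, RPIA and SLC26A2 were read by 1 probe above background.

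The 10 most raised genes among those measured on all 3 arrays included RGS5, a regulator of G-protein signalling, at 4.52-fold (log2 ratio 2.18 ± 0.40, n = 3, limma adjusted p = 3.52e-05). HMGA2, an architectural chromatin protein, was at 4.43-fold (2.15 ± 0.25). COX7C, measured on 2 arrays and so not ranked, had a log2 ratio of 1.98. FLG, which encodes the epidermal protein filaggrin, had a log2 ratio of 1.90 with a wide spread of 1.22 between arrays. Its other probes were at 1.61 and 0.93, the latter being the one used under the strict filter. All its probes were dim, at log2 intensities of 8.07 to 8.45. Its size also depended on the processing, with 3.05 with no background correction and 5.37 with the processed signals, where it exceeded RGS5 (2.36 and 2.45). Its limma adjusted p was 0.0571 without replicate 1 and 0.122 with a robust intensity trend in the variance. AREG, a ligand of the epidermal growth factor receptor, rose by 1.68 ± 0.39 and the lipid kinase gene PIP5K1B by 1.58 ± 0.05 on the log2 scale. IL1RAP, a subunit of the interleukin receptor complex, rose by 1.54 ± 0.21, with its 3 other probes at 1.39, 1.26 and 0.63. SPOCD1 (1.49 ± 0.12), the cap-binding protein gene EIF4E2 (1.45 ± 0.17), the transcriptional repressor gene HIC2 (1.44 ± 0.10) and the mitochondrial protein gene CCDC90B (1.43 ± 0.26) made up the rest. The other probe of HMGA2 had a log2 ratio of 0.33, that of CCDC90B 0.23 and that of RGS5 1.80.

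**Figure D1:**
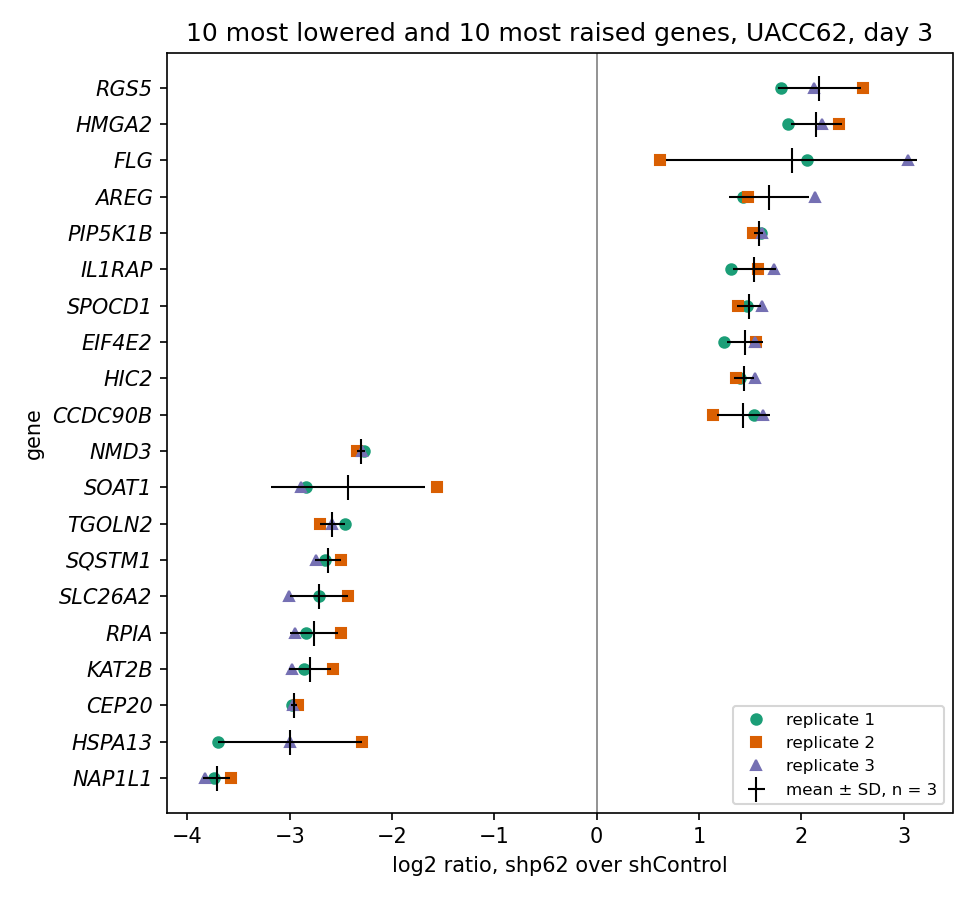
Log2 ratios of shp62 over shControl RNA (x axis) for the 10 most lowered and the 10 most raised genes measured on all 3 arrays (y axis). Symbols show replicates and black marks the mean ± SD. The points of CEP20 lie closest together, with an SD of 0.03, while those of FLG and SOAT1 spread most, with SDs of 1.22 and 0.75.

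Targets of NRF2, the transcription factor of the antioxidant response that p62 is known to regulate through KEAP1, were mostly lower. Of 27 measured, 22 fell, 1 rose and 4 did not pass, and the counts adjusted over the list alone were the same. NQO1, a quinone reductase, fell to a log2 ratio of -1.51 ± 0.18 (n = 3, limma adjusted p = 2.49e-05), the aldo-keto reductase gene AKR1C3 to -1.25 ± 0.15, GCLM of glutathione synthesis to -1.08 ± 0.12 and PIR to -0.73 ± 0.0073. ABCC1, an efflux pump of drug conjugates, was the member that rose (0.30). The median of the list was -0.62, and limma's camera with a preset correlation gave an adjusted p = 1.75e-06 for the 24 genes measured on all arrays (median -0.66). The call was lost with the correlation between genes estimated from the 3 arrays (adjusted p = 0.967 with an estimated correlation). NFE2L2, which encodes NRF2 and was chosen for a test of this group, had a log2 ratio of -0.29 (95% interval -0.45 to -0.14, limma adjusted p = 0.00968).

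Genes of mitosis were mostly lower too. In the list of the G2 and M phases 26 of 34 measured genes fell, 0 rose and 8 did not pass, over all genes and adjusted over the list alone. NUF2 of the kinetochore had a log2 ratio of -1.42 ± 0.13 (n = 3, limma adjusted p = 2.13e-05), DNA topoisomerase gene TOP2A -1.37 ± 0.33, the mitotic kinase gene AURKA -1.09 ± 0.20 and the kinetochore gene CENPF -1.05 ± 0.16. The list's median was -0.42 (camera adjusted p = 1.02e-07, adjusted p = 0.967 with an estimated correlation, which was 0.582), and it did not pass the rotation test fry (adjusted p = 0.0936). Among 36 genes of the G1 to S transition and DNA replication, 15 fell, 2 rose (RFC5 and POLE2) and 19 did not pass, with the same counts adjusted over the list alone. The clamp loader gene RFC3 fell to a log2 ratio of -1.39 ± 0.40, the replication clamp gene PCNA to -0.78 ± 0.14 and E2F2 to -0.56 ± 0.02. That list passed narrowly (median -0.14, camera adjusted p = 0.0496), in only 7 of 19 alternatives, and neither with an estimated correlation (adjusted p = 0.967) nor with fry (adjusted p = 0.0936). Of 16 replication-dependent histone genes and histone variants, 4 fell, 1 rose and 11 did not pass, and 4 fell and 0 rose adjusted over the list alone (camera adjusted p = 0.230). The variants H2AX (-0.82 ± 0.06) and H2AZ1 (-0.76 ± 0.08) led those that fell, with H3C4 at -0.37 ± 0.18 and H2AC8 at -0.32 ± 0.12.

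**Figure D2:**
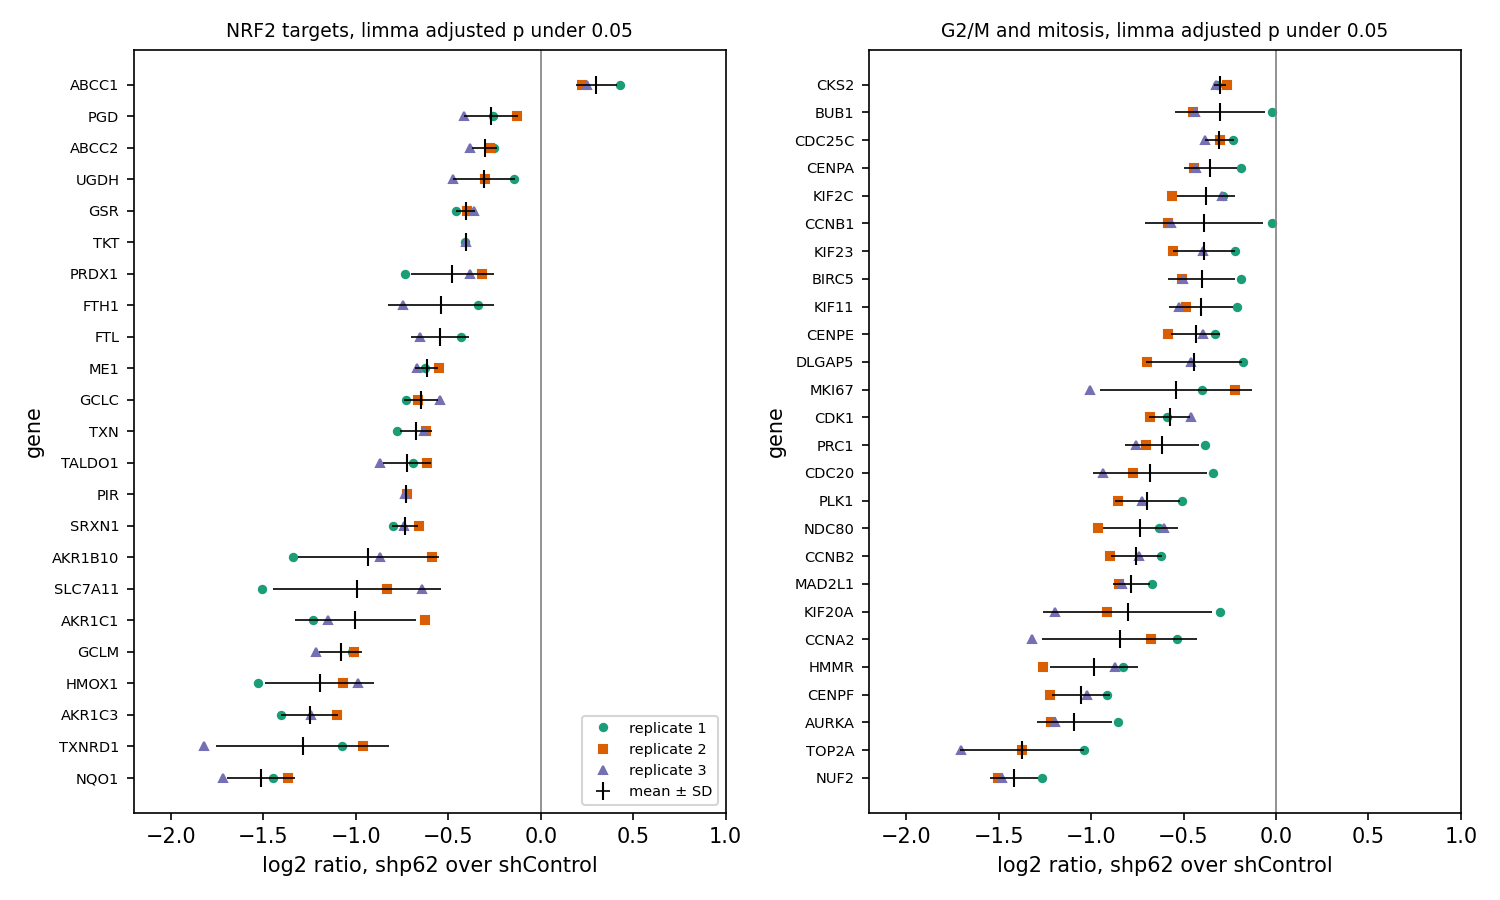
Log2 ratios of shp62 over shControl RNA (x axis) for the NRF2 targets and the genes of the G2 and M phases with a limma adjusted p under 0.05, on the y axis, with symbols for replicates and black marks for the mean ± SD. The 22 NRF2 targets and 26 mitosis genes that fell lie left of 0 and ABCC1 lies right of it, and a gene with 2 symbols was measured on 2 arrays.

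Short-lived mRNAs with AU-rich elements, many of them immediate early genes, were more often higher than lower. Of 35 measured, 16 rose, 4 fell (KLF6, JUN, CCND1 and KLF2) and 15 did not pass, also when adjusted over the list alone. AREG rose most, followed among the named members by the phosphatase gene DUSP2 (0.97 ± 0.01), the growth factor gene HBEGF (0.83 ± 0.11) and the cytokine gene LIF (0.67 ± 0.21, other probe 0.12). The median of the list was 0.18 (camera adjusted p = 0.0200, adjusted p = 0.967 with an estimated correlation). Among 22 NF-kB targets 8 rose, 3 fell (BIRC2, SOD2 and NFKB1) and 11 did not pass, with 9 rising adjusted over the list alone. CD83 (0.90 ± 0.18), the chemokine gene CCL2 (0.69 ± 0.08) and TNFAIP3 (0.68 ± 0.16), an inhibitor of the pathway, were higher and BIRC2 lower (-0.59 ± 0.07), while the list as a whole did not pass (camera adjusted p = 0.183). The 20 genes read as MAPK pathway output divided into 7 that rose, 6 that fell and 7 that did not pass (camera adjusted p = 0.844). SPRED1, an inhibitor of the pathway, fell to a log2 ratio of -1.47 ± 0.19 (other probe -0.44). Its relative SPRED2 rose to 0.86 ± 0.19 (other probe 0.20), with EMP1 at -1.02 ± 0.14 and PHLDB2 at -0.79 ± 0.14.

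The machinery of mRNA decay moved in both directions. Of 47 measured genes 12 rose, 11 fell and 24 did not pass, adjusted over the list alone as well (camera adjusted p = 0.844). XRN1, the main cytoplasmic exonuclease that degrades decapped mRNA, fell (-1.08 ± 0.10, n = 3, limma adjusted p = 4.16e-05) by its brighter probe. Its other probe was at -0.08 ± 0.15, with a log2 intensity of 8.74 against 10.6 for the brighter. Also lower were the decapping cofactor gene DCP1B (-0.93 ± 0.03) and the exosome subunit genes EXOSC2 (-0.80 ± 0.15) and EXOSC3 (-0.75 ± 0.13). Among 33 RNA-binding regulators of mRNA stability 10 rose, 11 fell and 12 did not pass (camera adjusted p = 0.936). FMR1 (-1.03 ± 0.25), HNRNPD, which binds AU-rich elements (-0.91 ± 0.12, with 1 of its 3 probes at -0.02), and QKI (-0.84 ± 0.28) fell. The other probes of QKI were at -0.51, -0.43 and -3.27 ± 1.33. SYNCRIP had a log2 ratio of -0.63 ± 0.12 with 1 of its 3 probes at 0.02. Of 24 mRNAs described as bound by the RNA-binding protein IGF2BP1, 6 rose, 10 fell and 8 did not pass, and 8 rose and 11 fell adjusted over the list alone (median -0.16, camera adjusted p = 0.728). HMGA2 led the rise in that list, with BTRC (0.60 ± 0.15) and ACTB (0.87 ± 0.10, n = 2) higher, while SRF was at -0.67 ± 0.15 with 1 of its 3 probes at 0.30.

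Autophagy genes other than SQSTM1 included members of both directions. In the core machinery 6 of 30 genes rose, 7 fell and 17 did not pass, with 8 falling adjusted over the list alone (camera adjusted p = 0.927). ATG4A, a protease that processes ubiquitin-like autophagy proteins, fell (-1.08 ± 0.20), with WIPI1 (-0.75 ± 0.10) and GABARAPL1 (-0.54 ± 0.10) lower and ATG13 of the initiating kinase complex higher (0.60 ± 0.06). Among 15 other receptors of selective autophagy 5 fell, 2 rose and 8 did not pass, and the list passed fry (adjusted p = 0.0425) and not camera (adjusted p = 0.844). NCOA4, the receptor for ferritin, was at -0.95 ± 0.53, CCPG1 at -0.76 ± 0.14, BNIP3 at -0.61 ± 0.02 and RETREG1 at -0.53 ± 0.06. Of 29 lysosome genes 7 fell, 4 rose and 18 did not pass, with 3 rising adjusted over the list alone (camera adjusted p = 0.811). The glycosidase genes GAA (-0.98 ± 0.06) and GLA (-0.76 ± 0.18) and the protease gene CTSF (-0.36 ± 0.04) fell and SGSH rose (0.60 ± 0.16). In the list of heat shock proteins and proteasome subunits 11 of 24 fell, 2 rose (HSPA8 and HSPB1) and 11 did not pass, in both adjustments. HSPE1 of the mitochondrial chaperonin had a log2 ratio of -1.34 ± 0.16 (n = 2), the inducible HSPA1A -0.87 ± 0.21, and the proteasome genes PSMD11 -0.69 ± 0.04 and PSMA3 -0.44 ± 0.12. The median of the 24 was -0.16 and that of the 17 in the set test, measured on all arrays, -0.24. These passed narrowly (camera adjusted p = 0.0488, adjusted p = 0.967 with an estimated correlation), and in only 6 of 19 alternatives. Genes measured on fewer arrays were left out of the set test. Among them were HSPA8 and HSPB1, the only members that rose, and HSPE1 and HSPD1, which fell.

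Genes of melanocyte identity and of the invasive melanoma state included members of both directions. In the pigmentation list 9 of 26 fell, 5 rose and 12 did not pass, and 10 fell and 6 rose adjusted over the list alone (camera adjusted p = 0.703). MLPH, which links melanosomes to myosin, fell to a log2 ratio of -1.27 ± 0.16 and the endothelin receptor gene EDNRB to -0.68 ± 0.10, while MCOLN3 (0.86 ± 0.08) and the receptor kinase gene MET (0.71 ± 0.25) rose. Of 29 genes of the dedifferentiated and invasive state 11 fell, 3 rose (ITGA5, EGFR and TNC) and 15 did not pass, with 12 falling adjusted over the list alone (median -0.18, camera adjusted p = 0.212). LOXL2 (-0.72 ± 0.09), WNT5A (-0.55 ± 0.12) and FGF2 (-0.54 ± 0.10) fell and the integrin gene ITGA5 rose (0.94 ± 0.19). In the list of matrix adhesion, which holds FERMT2, 9 of 31 fell, 8 rose and 14 did not pass (camera adjusted p = 0.936). FERMT2 was its lead member, with the caveolar gene CAV1 (2.01-fold, log2 SD 0.22) and the integrin gene ITGB1 (log2 ratio -0.71 ± 0.11) lower. TNS3 was higher (0.65 ± 0.04, other probe 0.14). Extracellular matrix genes divided into 6 that rose, 5 that fell and 16 that did not pass of 27 (camera adjusted p = 0.936), with MMP14 at -0.84 ± 0.27, COL5A2 at -0.76 ± 0.11, LUM at 0.65 ± 0.16 and FBN1 at 0.64 ± 0.22. Of 24 genes of the TGF-beta response 5 rose, 4 fell and 15 did not pass (camera adjusted p = 0.844), with TGFB1 at 0.73 ± 0.30, ID4 at 0.68 ± 0.04, SMAD7 at 0.50 ± 0.06 and TGFBR2 at 0.39 ± 0.05.

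Among metabolic genes, the cholesterol pathway moved in both directions. SQLE, an oxygenase of sterol synthesis, had a log2 ratio of -1.80 ± 0.07 (n = 3, limma adjusted p = 7.21e-06). Of 24 genes of the pathway 6 fell, 4 rose and 14 did not pass, and 7 fell and 5 rose adjusted over the list alone (camera adjusted p = 0.703). TM7SF2 was at -0.68 ± 0.06 with its other, dim probe (log2 intensity 7.65) at -0.11. LSS was at -0.60 ± 0.12 with 2 of its 4 probes above 0. In fatty acid synthesis 5 of 16 rose, 5 fell and 6 did not pass, with 6 rising adjusted over the list alone (camera adjusted p = 0.936). ACACA (1.04 ± 0.30, other probe 0.29) and ACSS2 (0.67 ± 0.06) rose and FADS1 fell (-0.86 ± 0.15). FADS2 was at -1.17 ± 0.31 with its other, dim probe (log2 intensity 7.855) at 0.04. Of 32 glycolysis and hypoxia genes 12 fell, 4 rose and 16 did not pass, and 13 fell and 6 rose adjusted over the list alone (median -0.12, camera adjusted p = 0.212). PDK1 (-1.27 ± 0.17, other probe -0.32), HK2 (-0.80 ± 0.15) and PFKFB4 (-0.65 ± 0.05) fell and the demethylase gene KDM3A rose (1.05 ± 0.01). In the mitochondrial respiratory chain 9 of 31 fell, 4 rose and 18 did not pass, with 10 and 5 adjusted over the list alone (camera adjusted p = 0.230). UQCRFS1 (-1.36 ± 0.19), NDUFV2 (-1.25 ± 0.04) and UQCRB (-1.25 ± 0.15) fell, and COX7C, measured on 2 arrays, rose (1.98 ± 0.31).

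Of 44 genes for cytosolic ribosomal proteins, 22 rose, 0 fell and 22 did not pass, with 24 rising adjusted over the list alone (median 0.27, and 0.096 over the 9 genes measured on all arrays). RPS15 had a log2 ratio of 0.87 ± 0.26, RPL35 of 0.62 ± 0.21, with 1 of its 4 probes at 0.09, and RPS2 of 0.84 ± 0.13, with 1 of its 3 probes at -0.05. Their spots are among the brightest, and 35 of the 44 were measured on 2 arrays because their spots on replicate 2 were marked as outliers. Of 169 other genes at or above the lower quartile of this list in log2 intensity (16.5), 67 rose and 16 fell, with a median of 0.17. The set test, which held the 9 genes measured on all arrays, did not pass (camera adjusted p = 0.0779, adjusted p = 0.967 with an estimated correlation), nor in 13 of 19 alternatives. The others, in which it passed, included the marked spots kept (8.54e-10), chosen after the data were seen, and replicate 2 left out (2.94e-07). Genes of ribosome biogenesis divided into 8 that fell, 4 that rose and 17 that did not pass of 29 (camera adjusted p = 0.844), with RRS1 at -0.78 ± 0.09 and, on 2 arrays each, FBL at 0.51 ± 0.11, NOP2 at 0.49 ± 0.13 and ODC1 at 0.47 ± 0.06.

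Markers of other cell types, fixed as a check of the culture, did not move together. Of 9 fibroblast markers 4 rose and 2 fell (camera adjusted p = 0.844), with the protease gene FAP lower by 1.99-fold (log2 SD 0.04), S100A4 at -0.65 ± 0.15, and LUM and DCN (0.47 ± 0.27) higher. Of 11 leukocyte markers 2 rose (camera adjusted p = 0.844), PTPRC by 0.37 ± 0.18 and LYZ by 0.47 ± 0.38, and CD68 (-0.21) and LCP1 (-0.17) did not pass. Of 9 keratinocyte and epithelial markers 2 fell (camera adjusted p = 0.844), CLDN1 (-0.83 ± 0.32) and KRT8 (-0.36 ± 0.06). Of 8 endothelial markers 1 rose (KDR, 0.45 ± 0.16) and 2 fell (ROBO4, -0.46 ± 0.38, and VWF, -0.25 ± 0.15), with a camera adjusted p = 0.927. Of 5 erythroid markers 2 rose, HBA2 at 0.39 ± 0.22 (other probe 0.04) and HBA1 at 0.35 ± 0.19, and HBB had a log2 ratio of 0.01 (camera adjusted p = 0.572). Several of these signals were dim: HBB, ROBO4, LYZ, PTPRC, HBA2, VWF and HBA1 had log2 intensities of 7.37 to 8.82. Others were brighter, such as FAP (12.2) and KDR (11.4). A change in so dim a signal does not show that the cell type was present. The counts adjusted over each of these lists alone were the same.

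Of the 35 lists fixed before the data were examined, camera with a preset correlation called 5, and 8 had an unadjusted p under 0.05. With an estimated correlation it called 0 at an adjusted or an unadjusted p under 0.05. That form rests on the few degrees of freedom of 3 arrays, so its lack of calls does not show that genes vary together. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction without setting them against other genes, called 5, of which NRF2 targets and the heat shock and proteasome list were among those camera called. The other 3 were the interferon response (fry adjusted p = 0.0344), the respiratory chain (0.0425) and the receptors of selective autophagy (0.0425), and the lists of mitosis (0.0936), replication (0.0936) and AU-rich mRNAs (0.101) did not pass fry. For the respiratory chain the set tests held the 27 genes measured on all arrays. Left out were COX7C, UQCRH and ATP5F1B, which rose, and ATP5PO, which did not pass, so most of that list's raised genes were not weighed. Median, mean and set test differed in sign for the lists of mRNA decay, RNA-binding regulators, MAPK output, TGF-beta response, fatty acid synthesis, ribosome biogenesis, apoptosis, p53 targets and endothelial markers, all with a median between -0.03 and 0.04. Where no counts adjusted over the list alone are given, they equalled those over all genes. Of 70 changed genes chosen by the naming rule that have another probe above background, 17 had such a probe at under 0.2 of the value given, in 6 of them with the opposite sign. The log2 intensity of these probes ranged from 7.65 (TM7SF2) to 15.7 (RPL35). Those of HBA2, FADS2, LIF and XRN1 were dim too, at 7.85 to 8.74, while those of HMGA2, SYNCRIP and RPS2 were bright, at 13.6 to 15.3. The count does not tell a dim probe from a conflicting one.

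**Figure D3:**
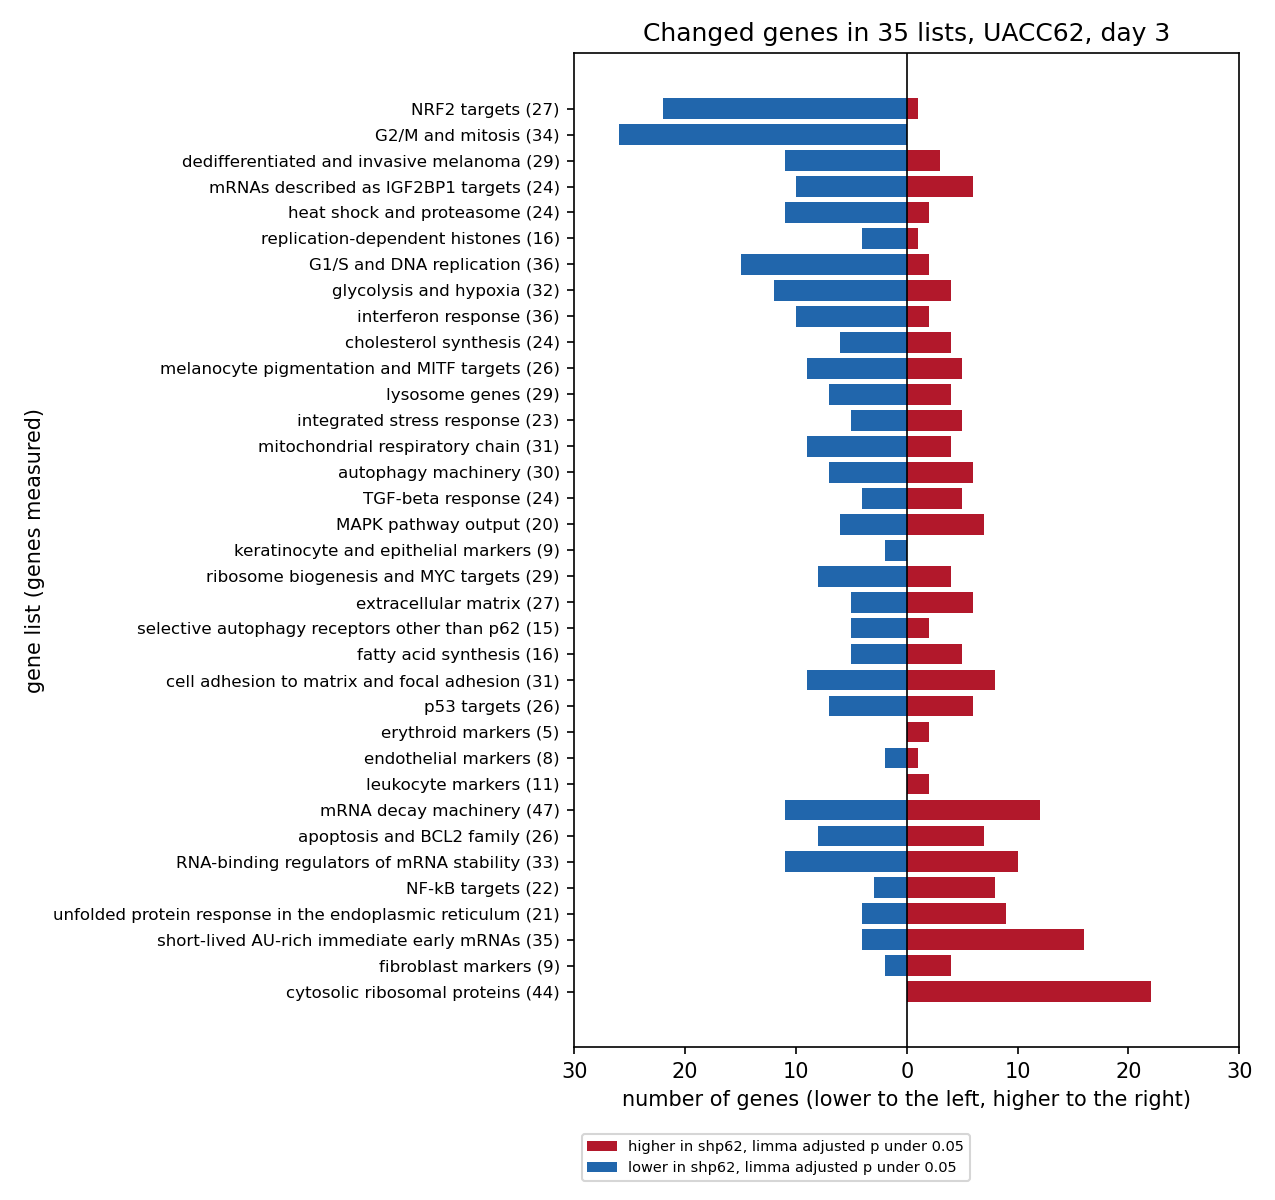
Number of genes (x axis) called lower (blue, to the left) and higher (red, to the right) in shp62 than in shControl RNA at a limma adjusted p under 0.05 in each of 35 gene lists (y axis, with the number of genes measured), ordered by median log2 ratio. The mitosis list has 26 genes to the left and 0 to the right, the NRF2 list 22 and 1, and the ribosomal proteins 0 and 22.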

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

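The count over exchanged channels was chosen after its result was seen, and the other tests in this part before. Groups of 3 samples were not tested for outlying samples.

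A signal lies in probes outside the gene-level comparison. Of 11245 transcripts without a current symbol, limma called 1452 at an adjusted p under 0.05, of which 493 were higher and 959 lower in depleted cells.

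The share of changed genes is high for 3 arrays. Exchanging the 2 RNAs on 1 array gives 4 splits with the real one, and 1 of the 4 called as many genes. Limma called 5724 in the real split and at most 0 in the others, which had 7 to 96 genes at an unadjusted p under 0.05. Since the arrays resemble each other, reversing 1 widens the spread of each changed gene, so these low counts are no level for chance. A dye effect shared by the arrays would give them too, and 4 splits are too few to give a share under 0.05. Against a dye bias of single probes as the whole cause, the next brightest probe had the same direction in 84.96% of the called genes that have such a probe (1909 of 2247). The exact 95% interval, 83.4% to 86.4%, lay above the 80% set in advance, while genes not called reached 63.7%. That interval treats genes as independent, though all were read on the same 3 arrays, so it may be too narrow. Sizes held less well: in called genes of at least 2-fold the next probe's log2 ratio was at a median 0.575 of the first's. A dye effect on a gene's sequence as a whole and silencing of other transcripts by the single shRNA stay open, since no array swapped the dyes and no other shRNA was used. Loss of p62 is the biological explanation the design names, as a hypothesis.

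Most NRF2 targets (22 of 27) and mitotic genes (26 of 34) fell, though both lists lost camera's call (adjusted p = 0.967 with an estimated correlation) and the mitosis list did not pass fry (adjusted p = 0.0936). Against an intensity-dependent bias left by the normalization, the median of each list on each array lay at or below percentile 0.03 of 10000 random lists matched on intensity. On a fall of the NRF2 transcript as the source of the lower targets, NFE2L2 had a log2 ratio of -0.2944. Its 95% interval (-0.45 to -0.14) lay above the list's median of -0.62, so it fell, but by less than the median target. A target need not fall by the same amount as the transcript of its regulator, so this source stays open. Also left open are effects of the shRNA other than through p62. So are genes within a list that vary together, since 3 arrays estimate that correlation poorly. No list passed with it, but that form of camera also rests on the few degrees of freedom of 3 arrays. The heat shock and proteasome list, with an estimated correlation of -0.0555, went from an unadjusted camera p = 0.00557 to 0.0963. The loss of calls thus does not show that genes vary together. Loss of p62, the biological difference the design names, stays open for both lists and untested, since neither NRF2 activity nor growth was measured on these arrays.

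The steepest falls include genes that fell by more than the target of the shRNA. Of the 6 genes, 3 have another probe above background, with log2 ratios of -0.4145 (HSPA13), -0.71 (CEP20) and -1.96 (KAT2B), and 1 of these 3 probes lies below -1. All 3 lie below 0, so a fault of a single probe may set the size of the fall more than its direction, but the values do not settle it. The other probe was dimmer in each case, for CEP20 at a log2 intensity of 8.76 against 13.0. For NAP1L1, RPIA and SLC26A2 a fault of the probe cannot be told apart from a real fall, since each has 1 probe above background. Silencing of these transcripts by the same shRNA is a candidate explanation that was not tested, and so is an effect of p62 loss.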

How the results depend on the processing

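The alternatives with scaling over probes above background, with outlier spots kept and with unnamed probes tested too were chosen after the data were seen, and the others before. Signal over background limited the gene set more than the calls: with no filter on dim probes 16417 genes were tested and with the strict filter 13178. SQSTM1 kept its direction in all 19 alternatives, between -2.97 and -2.57, and passed in 17, with adjusted p from 2.12e-10 to 0.161. Leaving out each replicate gave it values from -2.70 to -2.57.

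Median centring called 7 genes, 0 higher and 7 lower (all 7 also called by loess), with SQSTM1 at -2.58 (adjusted p = 0.0555), against 55.1% lower of 5724 with loess, and 586 genes had an unadjusted p under 0.05. Before loess the ratio fell by 0.32 per log2 unit of intensity on replicate 2 and rose by 0.12 and 0.10 on replicates 1 and 3, and centring leaves these trends in. Scaling all spots between arrays called 0 genes, 0 higher and 0 lower (limma, 4259 at an unadjusted p under 0.05), with SQSTM1 at -2.97 (adjusted p = 0.161). Its factors of 0.724, 2.15 and 0.644 widen the ratios of replicate 2. Factors from probes above background gave 2900 genes (1338 higher, 1562 lower). A threshold of at least 2-fold left 345 genes (61 higher, 284 lower) and an adjusted p under 0.01 left 3530 (1435 higher, 2095 lower), by construction. Leaving out 1 replicate gave 3122 to 5307 genes, 1160 to 2494 higher and 1962 to 2840 lower, the lowest without replicate 1, where 3086 of the 3122 were also called with all arrays. In every other alternative the gene counts stayed within 1.5 times, but the majority turned to higher with the authors' matrix (3538 higher, 3143 lower, 47.0% lower) and the processed signals (3484 higher, 3186 lower, 47.8% lower). The cause was not tested. The quantile-type normalization (5726 genes) left each probe's log2 ratio unchanged, so its count could hardly differ.

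Of 35 lists, 5 passed, against 3 with no background correction, offset 16, the processed signals, scaling of all spots, the authors' matrix, the strict filter and array weights, and 0 with an estimated correlation. Fry called 5, of which 2 were among camera's 5. The cause was not tested. The NRF2 list passed in 18 of 19 alternatives (medians -0.76 to -0.60), the mitosis list in 17 (-0.54 to -0.33), the AU-rich list in 17 (0.16 to 0.26), the replication list in 7 and the heat shock list in 6. Each of these counts includes the variance trend, which did not enter the set test and so repeated the main result. The quantile-type normalization, which left each probe's ratio unchanged, could hardly differ either. Leaving out each replicate gave 4 to 5 lists. Of 2950 values of named genes under alternatives, 2606 kept their side of the threshold, 0 were counted as reversed, and 336 lost the call, 142 of them with median centring and 149 with scaling of all spots. A reversal was counted only where the gene passed in the main fit or in the alternative. With every probe tested on its own, only the probe of the main fit was compared, so a conflicting probe could not show there.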

Other observations

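The groups below were fixed before the data were examined and carry no weighing of explanations. Of 36 interferon response genes 10 fell, 2 rose (USP18 and OAS3) and 24 did not pass, also when adjusted over the list alone. ISG20, an exonuclease with antiviral activity, had a log2 ratio of -1.47 ± 0.06 (n = 3, limma adjusted p = 1.34e-05), IFI44 -1.11 ± 0.14, the RNA sensor relative DHX58 -0.58 ± 0.03 and IFIT1 -0.57 ± 0.03. The list did not pass camera (median -0.11, and -0.12 over the 35 genes in the set test, adjusted p = 0.114) and passed fry (adjusted p = 0.0344). Among 26 p53 targets 7 fell, 6 rose and 13 did not pass (camera adjusted p = 0.936). TP53INP1, which acts in autophagy and cell death, was at -1.68 ± 0.41 and BAX at -0.86 ± 0.29 (other probe -0.18). AEN was at -0.57 ± 0.15 and the death receptor gene FAS at 0.79 ± 0.20. In the apoptosis list 8 of 26 fell, 7 rose and 11 did not pass, with 8 rising adjusted over the list alone (camera adjusted p = 0.936). PMAIP1, which promotes cell death, fell to a log2 ratio of -0.85 ± 0.22, while MCL1, a survival protein gene, was at -0.72 ± 0.16 with 1 of its 3 probes at 0.36.

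Of 23 genes of the integrated stress response 5 rose, 5 fell and 13 did not pass (camera adjusted p = 0.844). The cystine transporter gene SLC7A11, also an NRF2 target, was at -0.99 ± 0.46, CEBPB at -0.67 ± 0.10 (other probe -0.13), DDIT4 at -0.62 ± 0.13 and AARS1 at 0.47 ± 0.07. Of 21 genes of the unfolded protein response 9 rose, 4 fell and 8 did not pass (median 0.16, and 0.035 over the 17 genes in the set test, camera adjusted p = 0.936), with DNAJB9 at 0.56 ± 0.13 and DNAJC3 (-0.79 ± 0.13), SYVN1 (-0.60 ± 0.08, other probe -0.04) and SEL1L (-0.44 ± 0.07) lower. The counts adjusted over each of these lists alone were the same.

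Replicate 2 differed from the others before loess. Its ratios, background-corrected and centred on the median, correlated with those of replicates 1 and 3 across all spots with r = -0.54 and -0.43, against 0.91 between 1 and 3. Across spots above background these were r = -0.31 and -0.16, against 0.87. After loess the gene-level values were 0.85, 0.80 and 0.86. Its outlier spots were bright, with a median log2 intensity of 16.3 against 8.30 for all its spots. For 10 spike-in transcripts the mean log2 ratio was 0.12, -0.12 and 0.51 on replicates 1, 2 and 3, with replicate 3 highest for 10 of 10 and replicate 2 lowest for 10 of 10.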
